A study of Mus musculus with 6 samples.

How the data were processed

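RNA was extracted with TRIzol from thymuses of C57BL mice aged 5 weeks, and polyadenylated RNA was made into libraries with a NEBNext kit and sequenced, per the labels. The 3 control and 3 irradiated libraries (6 Gy of X-rays, collected after 24 h) were grouped by their labels, and no library was left out.

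The deposited tables give 1 FPKM value per library, computed by the authors, for mRNA and for lncRNA transcripts. The same tables give a log2 fold change, a p-value and an adjusted p-value, which the authors computed with DESeq2 1.10.1 per the submitters' processing notes. Aligner, counting tool, strand use and annotation release are not given in the sources used here. Of the Ensembl transcripts found in GENCODE M21, which is on the mouse build GRCm38, 99.81% in the mRNA table and 99.91% in the lncRNA table have the same start and end. The deposited group means were checked against the libraries, and 0 lines differed by over 0.001 FPKM.

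The mRNA table holds 59179 transcript lines of 21954 genes. All 12860 genes with several transcripts and a value above 0 repeat 1 set of values on each line, so 1 value per gene was used. The lncRNA table holds 53063 lines, of which 62 carry only overflow text and were dropped. Its 53001 transcripts belong to 23336 genes, and their FPKM values were summed to genes. Of these transcripts 36176 belong to genes of the type protein_coding and 15769 to genes of the type lncRNA, and 12534 genes are in both tables. By M21 transcript type, 21838 are retained introns, 15844 processed transcripts, 9089 lincRNA and 4510 antisense. Gene names that had been turned into dates, 27 in the mRNA table and 20 in the lncRNA table, were restored from the gene identifier.

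Depth was estimated from the most common smallest value of FPKM times length in kilobases among genes with 1 transcript, taken as 1 fragment. In units of 1000 x 1000 fragments it came to 22.3, 23.2 and 21.9 in control replicates 1, 2 and 3 and to 24.6, 25.6 and 24.4 in irradiated replicates 1, 2 and 3, and 1 fragment in a transcript of 1 kb is then worth 0.0391 to 0.0456 FPKM. Summed FPKM of the mRNA table was 265813, 274422 and 269606 in the controls and 249245, 316531 and 305776 in the irradiated libraries, while the lncRNA table summed to 79142, 79152 and 84166 FPKM in the controls and to 81980, 51208 and 57559 FPKM in the irradiated libraries.

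The design, fixed before the files were opened, assumed counts and a test for counts, and named limma for FPKM. The deposited values are FPKM, so the limma branch was used: log2(FPKM + 0.1), genes averaging at least 0.5 FPKM, a group-only model and empirical Bayes moderation with an abundance trend (limma 3.58.1 in R 4.3.3). Each table was tested alone, with Benjamini-Hochberg adjustment over its genes and a threshold of adjusted p under 0.05. Log2 fold changes are irradiated minus control. A second count asked for a log2 fold change of at least 1 in size. Groups of 3 and 3 do not overlap by chance in 10% of genes.

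Before the data were examined, 34 gene lists were fixed, covering p53 targets, mitosis, DNA replication, 2 repair pathways, the BCL2 family, stages of thymocytes, thymic stroma, blood cells, fat, cytokine and hormone responses, 3 parts of the PI3K-AKT pathway, regeneration factors, lysosomes and mitochondrial and ribosomal protein genes. They hold 721 genes, of which 712 were found in the mRNA table. A list of 62 known lncRNA genes was fixed as well. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each in limma and Benjamini-Hochberg adjusted over the 34 lists. Camera compares a list with all other genes, while fry asks whether the genes of the list changed at all. Members were also counted after adjustment over the list alone. Lists of airway epithelium, skeletal muscle, parathyroid and lung genes and the histone, Zfp, Cyp and Ccl families were added after the values were seen.

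Genes named in the text follow a rule set in the design. In the mRNA table these are the 10 largest increases and the 10 largest decreases with adjusted p under 0.05, at least 5 FPKM in the higher group, groups that do not overlap and a symbol not of the Gm, Rik or LOC kind. In each list they are the 4 members with the smallest adjusted p. In the lncRNA table they are the 5 largest changes each way with at least 0.5 FPKM in the higher group and groups that do not overlap, and every known lncRNA gene past the threshold. Other list members are named for what their values show beside these, passing or not.

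Each tested lncRNA gene was paired with the nearest tested mRNA-table gene of another identifier within 100 kb. Spearman's rho and the share of lncRNA genes past the threshold whose neighbour moved the same way were compared with 100000 permutations of the neighbours. Shares of summed FPKM were compared with exact two-sided permutation tests, which with 3 and 3 libraries cannot go below p = 0.1. Principal components and Pearson correlations used log2(FPKM + 0.1). Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

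The code was tested on simulated data. In 5 runs of 12487 mRNA genes, limma called 44.0%, 83.4% and 93.5% of simulated log2 fold changes of 1, 2 and 3 in size, each in the right direction, and 0.0830% of unchanged genes. In the lncRNA table (8480 genes per run) it called 13.2%, 70.6% and 88.2%. Over the 5 mRNA runs 250, 499 and 248 genes were changed by 1, 2 and 3 and 61438 were unchanged. The simulated changes were thus far rarer than the calls in the real data, and these rates need not hold there. For 1000 simulated pairs, correlations of 0, 0.3 and 0.6 came back as -0.03, 0.23 and 0.61, with the right neighbour in 100% of pairs.

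Alternatives fixed in advance were pseudocounts of 1 and 0.01, quantile normalization, 2 other filters and a replicate block. Also fixed were each library left out of the gene, list and neighbour tests, a threshold of 0.01 and single transcripts. Other neighbour distances, pairs that do not overlap and shares without the most abundant genes were fixed as well. Scaling by median ratios and by summed FPKM, lncRNA genes alone, mRNA-table factors for the lncRNA table, transcripts against the mRNA of their own gene and the authors' deposited table were added after the values were seen. Sequencing reads were not used here.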

Results

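The thymus is the organ in which T cells mature from bone marrow precursors, and its dividing cortical thymocytes are among the cells most easily killed by ionising radiation. Polyadenylated RNA, per the labels, was sequenced from thymuses of C57BL mice aged 5 weeks, in 3 unexposed controls and in 3 mice killed 24 h after X-ray exposure to 6 Gy. Abundance was given as FPKM, fragments scaled by transcript length and sequencing depth, in an mRNA table of 21954 genes and a lncRNA table of 53001 transcripts. The number of mRNA genes at 1 FPKM or more was 11274 to 11453 in the controls and 12853 to 13711 in the irradiated libraries. The labels give 3 mice per group without tying each library to an animal in words, so p-values measure the spread between these samples.

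The libraries parted by group. The first principal component of log2 values held 83.7% of the variance, with the controls at -102 to -95.8 and irradiated replicates 1, 2 and 3 at 54.4, 134 and 108. The Pearson r across genes was 0.979 or higher between controls, 0.824 to 0.931 between irradiated libraries and 0.619 to 0.815 between the groups. Genes are not independent replicates, and these values describe the libraries only.

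The first comparison addresses which protein-coding genes differed between irradiated and control thymus 24 h after exposure. Genes that define cortical thymocytes were among the most reduced. Rag1, a subunit of the recombinase that assembles T cell receptor genes (ENSMUSG00000061311, chromosome 2, 101638282 to 101649501), averaged 548 ± 40.9 FPKM in controls and 1.60 ± 0.959 FPKM in irradiated thymus (SD, n = 3 each). Its log2 fold change was -8.56 ± 0.49 (SE, limma adjusted p = 5.42e-05). The other subunit, Rag2 (chromosome 2, 101624718 to 101632529), went from 48.7 ± 2.66 to 0.290 ± 0.272 FPKM, a log2 fold change of -7.30. Dntt, the template-independent polymerase that adds bases at receptor junctions (chromosome 19, 41029275 to 41059525), went from 395 ± 23.8 to 7.17 ± 6.33 FPKM, a log2 fold change of -6.18. Among genes that met the naming rule, the largest increase at the pseudocount of 0.1 was that of Serpina3n, a secreted serine protease inhibitor (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), from 0.968 ± 0.180 to 129 ± 27.0 FPKM, a log2 fold change of 6.92 ± 0.20 (SE, limma adjusted p = 4.47e-05).

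Of 14001 mRNA genes tested with limma on log2(FPKM + 0.1), 5933 were higher and 2920 lower in irradiated thymus at a Benjamini-Hochberg adjusted p under 0.05. With a log2 fold change of at least 1 in size, 4699 were higher and 1439 lower. The groups did not overlap in 9910 genes (70.8%), against 10% by chance. The split depended on the scaling between libraries: the median log2 fold change of all tested genes was 0.40 in the deposited FPKM, -0.07 after quantile normalization and 0.02 after median-ratio scaling. Quantile normalization gave 3501 higher and 4403 lower genes, and median-ratio scaling 4655 higher and 4558 lower. Medians of the gene lists that camera called are therefore given below also relative to the median of all genes over the 4 scalings tried.

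The other genes with the largest decreases were Tdrd5 (-6.37), Tctex1d1 (-6.29), Arpp21 (-6.05), the histone genes Hist1h3b (-6.01) and Hist1h2an (-5.75), the transporter gene Slc16a5 (-5.51) and the acetylcholine receptor subunit gene Chrna9 (-5.36), all log2 fold changes. Hist1h3b and Hist1h2an have near-identical copies that can share reads, so their values are uncertain. The other increases were those of Pdpn (6.40), Sept2 under its second identifier ENSMUSG00000116048 (6.19), Scgb1a1 (6.07), the skeletal muscle actin gene Acta1 (5.96), Itih4 (5.74), the protease inhibitor gene Slpi (5.72), Cidea of fat cells (5.68), the airway secretory gene Bpifa1 (5.62) and the macrophage gene Gpnmb (5.62). With a pseudocount of 0.01, Pdpn (8.65), Sept2 (8.40), Acta1 (7.54) and Scgb1a1 (7.53) stood above Serpina3n (7.04). In the authors' deposited table Scgb1a1 (10.23), Acta1 (7.99), Bpifa1 (7.64) and Itih4 (7.46) stood above Serpina3n (6.82). Scgb1a1, which encodes a secretory protein of airway club cells, measured 811 FPKM in irradiated replicate 2 against 1.79 FPKM in irradiated replicate 1. Without irradiated replicate 2 its log2 fold change was 3.18 and that of Bpifa1 3.73. Over all leave-one-out fits those of Acta1, Itih4, Slpi and Cidea ran from 4.57 to 7.41, 4.84 to 7.32, 4.61 to 7.30 and 4.44 to 6.94, and those of Pdpn and Sept2 from 5.66 to 7.47 and 4.79 to 8.99. The call for Scgb1a1 (limma adjusted p = 0.0475) was lost without any of the controls, at adjusted p of 0.0772 to 0.134, and after quantile normalization, at 0.119. The Sept2 identifier overlaps another Sept2 model and measured 33.6 FPKM in control replicate 1 and 0 in the other controls, so its value is uncertain. Its limma call was lost without control replicate 2 (adjusted p = 0.116), control replicate 3 (0.120), irradiated replicate 2 (0.0761) or irradiated replicate 3 (0.0859). In the authors' deposited table the log2 fold change of this Sept2 identifier was 1.89 and did not pass (DESeq2 adjusted p = 0.462).

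**Figure D1:**
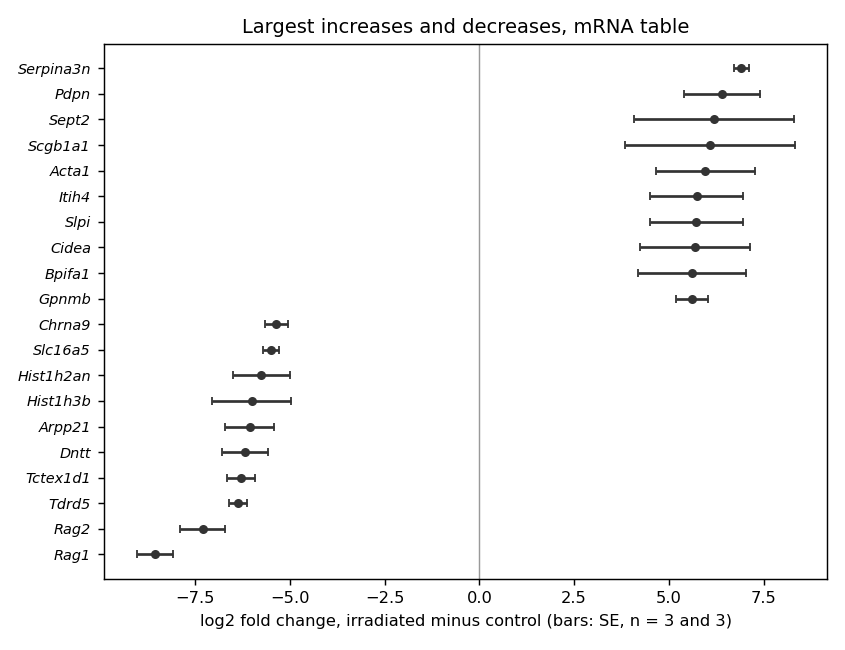
Log2 fold change (irradiated minus control, on log2(FPKM + 0.1)) of the 10 mRNA-table genes with the largest increase and the 10 with the largest decrease, with bars for the standard error (n = 3 and 3). Rag1 stands at -8.56 and Serpina3n at 6.92, and the widest bar is that of Scgb1a1, with a standard error of 2.24.

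Genes of double-positive thymocytes fell. Of 18 genes of double-positive thymocytes, the cortical cells that carry both CD4 and CD8, 16 fell and none rose, with a median log2 fold change of -3.83, which lay -4.28 to -4.22 from the median of all genes over the scalings. Cd8a went from 248 ± 17.6 to 13.6 ± 3.39 FPKM (SD, n = 3), Cd8b1 by a log2 fold change of -4.47 and Ccr9, a chemokine receptor, by -5.23. Cd24a (-0.29) and Cd1d1 (-0.46) did not pass. The camera adjusted p of this list was 5.42e-12, and adjusted p = 0.369 with an estimated correlation. Of 16 genes of the T cell receptor complex and its proximal signalling, 14 fell, or 15 adjusted over the list alone, among them the kinase gene Lck (338 ± 4.88 to 48.9 ± 8.99 FPKM), Cd247 (-2.79), Rhoh (-2.93) and the costimulatory receptor gene Cd28. Its median was -1.85 (camera adjusted p = 2.7e-09; adjusted p = 0.407 with an estimated correlation) and lay -2.26 to -1.88 from the median of all genes over the scalings.

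Genes of the stages before and after the double-positive stage went both ways. Among 20 genes of mature single-positive T cells, 8 rose, including Klf2 (1.46), a transcription factor of thymic exit, and S1pr1 (1.13), a receptor that these cells need to enter the blood. In the same list 5 fell, including Cd27 (-3.20), Cd5 (-1.54) and Gimap6 (-1.50). The list median was 0.42, its mean -0.03 and the direction of camera down (adjusted p = 0.599), so the signs differed. After quantile normalization 6 mature T cell genes rose and 6 fell, after median-ratio scaling 3 and 7, and after summed-FPKM scaling 5 and 5. Without control replicate 1 the counts were 3 and 5, and without control replicate 2 they were 5 and 5. Among 15 early thymocyte genes 10 rose, among them Hes1 (2.56), a target of Notch signalling, Meis1 (2.55) and Bcl11a. Ptcra, the partner of the T cell receptor beta chain before the double-positive stage, went from 10.6 ± 1.53 to 0.228 ± 0.208 FPKM (SD, n = 3), and Mycn fell by 1.18 on the log2 scale. Cd34 and Erg, which also rose, are expressed by endothelium, and Spi1 by myeloid cells. Adjusted over the list alone, 11 early thymocyte genes rose and 2 fell, and the camera adjusted p was 0.0935, with a median of 1.48 that stood at least 0.33 above that of all genes over the scalings. Fry, which does not compare a list with other genes, called the early list as higher (adjusted p = 0.00063). After quantile normalization 5 early genes rose and 2 fell. Of 9 regulatory T cell genes, 4 rose, including Foxp3 (1.42), the lineage transcription factor, Ikzf4 (1.42) and Capg (3.05), which macrophages also express, and Ikzf2 fell (-1.63). Camera gave an adjusted p of 0.939, the list median of 0.34 turned to -0.22 after quantile normalization and to -0.04 after median-ratio scaling, with Foxp3 at -0.22 (limma adjusted p = 0.609) and Ikzf4 at 0.23 (0.501) after quantile normalization. There 1 regulatory gene rose and 2 fell, against 3 and 2 after median-ratio scaling and 4 and 2 without irradiated replicate 1. The counts of the double-positive, mature and regulatory lists were the same adjusted over the list alone.

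**Figure D2:**
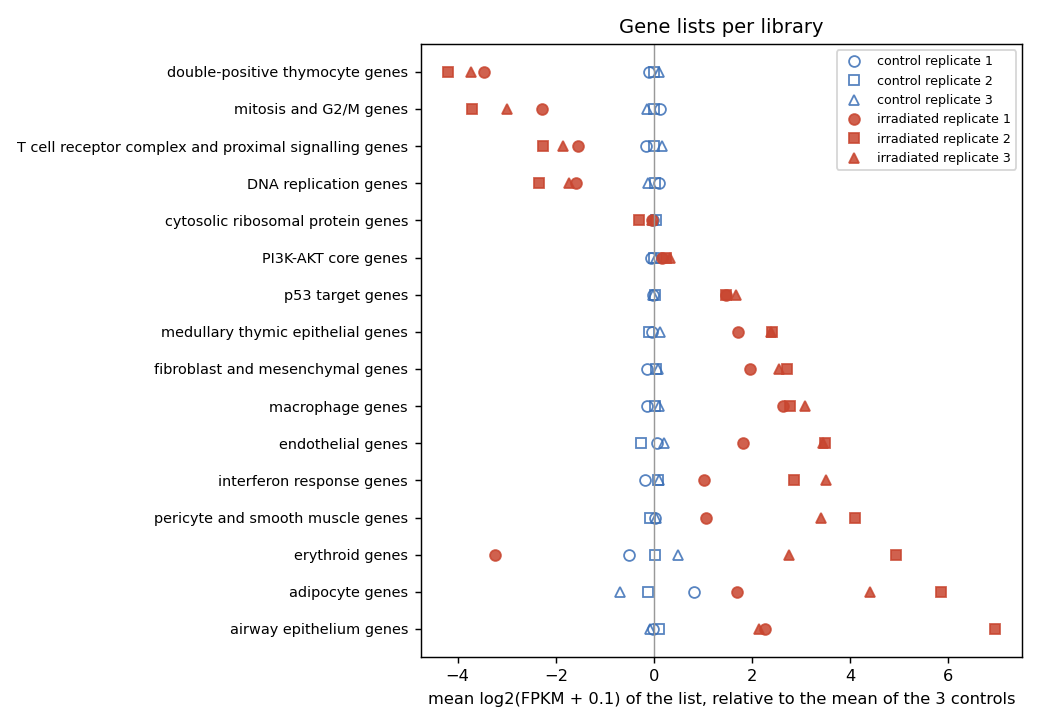
Mean log2(FPKM + 0.1) of the members of 16 gene lists in each of the 6 libraries, relative to the mean of the 3 controls (open blue symbols, controls; filled red symbols, irradiated; symbol shape, replicate number). Double-positive thymocyte genes stand at -3.46, -4.20 and -3.73 in irradiated replicates 1, 2 and 3, and airway epithelium genes at 2.27, 6.96 and 2.14.

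Genes of cell division fell together. All 30 mitosis and G2/M genes were lower, with a median log2 fold change of -2.90 (camera adjusted p = 2.45e-16; adjusted p = 0.407 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, went from 19.4 ± 3.96 to 2.74 ± 0.883 FPKM (SD, n = 3), Bub1b of the spindle checkpoint by a log2 fold change of -2.79, Kif20a by -2.46 and Nusap1 by -3.81. Of 30 DNA replication genes 29 fell, with a median of -1.94 (camera adjusted p = 5.8e-15; adjusted p = 0.407 with an estimated correlation). Mcm2 of the replicative helicase fell by 2.02 on the log2 scale, Uhrf1 by 2.92, Gins1 by 2.18 and the clamp loader gene Rfc4 by 2.29, while Rfc3 was at -0.16 (adjusted p = 0.342). Both counts were the same adjusted over the list alone. Relative to the median of all genes, the medians lay -3.54 to -3.29 and -2.35 to -2.22 away over the scalings.

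DNA repair genes mostly fell. A smaller thymocyte share, weighed below for other lists, could also lower these and the cell division genes. This was not tested. Among 23 genes of homologous recombination and the DNA damage checkpoint, 18 fell, or 19 adjusted over the list alone, including Fanci (-2.44), Bard1 (-2.15), Blm (-1.92) and Fancd2 (-1.92). The list median was -1.69 (camera adjusted p = 1.9e-07; adjusted p = 0.415 with an estimated correlation). Trp53bp1 (0.30) and Nbn (0.21) did not pass. Of 10 genes of non-homologous end joining, the pathway that also closes receptor gene breaks, 6 fell and 2 rose, with the same counts adjusted over the list alone and 7 and 1 after quantile normalization. Lig4, its ligase, went from 19.9 ± 0.0538 to 1.84 ± 0.152 FPKM (SD, n = 3), Xrcc6 by a log2 fold change of -2.77 and Xrcc4 by -1.33. Xrcc5 (1.01) and the polymerase gene Poll (1.51) rose, the call for Poll being lost after quantile normalization at an adjusted p of 0.0565. The median was -0.70 (camera adjusted p = 0.00928; adjusted p = 0.407 with an estimated correlation). Over the scalings the medians of the recombination and end joining lists lay -2.17 to -2.09 and -1.19 to -1.10 from that of all genes.

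Targets of the transcription factor p53, which is activated by DNA breaks, mostly rose. Of 34 tested, 23 rose and 5 fell, or 24 and 5 adjusted over the list alone, with a median log2 fold change of 1.52, which lay 1.11 to 1.16 above the median of all genes over the scalings. Plk2 went from 0.845 ± 0.0763 to 17.6 ± 2.53 FPKM (SD, n = 3), Phlda3, an inhibitor of AKT, from 7.35 ± 0.819 to 82.4 ± 15.4 FPKM, Zmat3 by a log2 fold change of 2.39 and Dcxr by 3.02. The cell cycle inhibitor gene Cdkn1a rose by 5.04, and the pro-apoptotic genes Bax, Bbc3 and Pmaip1 by 1.32, 1.42 and 1.67. The 5 that fell were Btg2 (-1.69), Tnfaip8 (-1.78), Fas (-0.85), Trp53inp1 (-0.90) and Pidd1 (-0.69), while Mdm2 was at 0.16 (adjusted p = 0.354). The camera adjusted p was 0.00603, and adjusted p = 0.407 with an estimated correlation. Of 22 genes of the BCL2 family and caspases, 6 rose, including the survival gene Bcl2l2 (1.95), and 5 fell, including the pro-apoptotic genes Bid (-0.87) and Bmf (-1.01), with 5 and 5 adjusted over the list alone. Its median (0.21) and camera direction (down, adjusted p = 0.594) differed in sign, and the median was -0.07 after quantile normalization and -0.18 after median-ratio scaling, with 2 higher and 6 lower in the former and 3 and 8 in the latter. Without control replicate 2 the counts were 5 higher and 2 lower, and without control replicate 3 they were 4 and 3. Bcl2a1a (1.34, lost after quantile normalization at a limma adjusted p of 0.118) has near-identical copies and is uncertain.

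Genes of medullary thymic epithelium, stroma, vessels and macrophages rose, as did part of those of cortical epithelium. All 13 tested medullary epithelial genes were higher, with Epcam, an epithelial adhesion gene, going from 6.82 ± 0.709 to 48.0 ± 5.77 FPKM (SD, n = 3) and Avil and Trpm5, genes of tuft cells, rising by 2.45 and 2.43. Aire, the regulator of self-antigen expression, rose by 0.78, and Ccl21a, which has near-identical copies and is uncertain, by 3.31. The median was 2.32 (camera adjusted p = 0.00132; adjusted p = 0.415 with an estimated correlation). Among 15 cortical epithelial genes 10 rose, including the transcription factor genes Pax1 (2.72) and Pax9 (2.82) and the chemokine gene Cxcl12 (2.52). Psmb11 (-0.78), Prss16 (-0.99) and Ccl25 (-1.37), also cortical epithelial genes, did not pass. The cortical list did not pass camera (adjusted p = 0.0943, and 0.0089 after quantile normalization) but passed fry, as higher (adjusted p = 0.00507). After median-ratio scaling 9 cortical genes rose and 2 fell, against 10 and 3 without irradiated replicate 1, and after quantile normalization 8 medullary genes rose. Of 20 fibroblast genes 19 rose, among them Mgp (13.5 ± 3.73 to 220 ± 7.41 FPKM), Gas6 (3.32) and Postn (1.90), and Thy1, which thymocytes also express, fell by 2.91. The fibroblast median was 2.76 (camera adjusted p = 5.51e-05; adjusted p = 0.407 with an estimated correlation).

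Of 19 endothelial genes 17 rose, including Flt1 (4.15), a receptor of vascular growth factor, Emcn (3.13), Esam (3.02) and Egfl7 (2.69), while Pecam1 was at 0.12 and Selplg at -0.01. The mean of the endothelial genes over the controls was 1.83 in irradiated replicate 1 and 3.50 and 3.45 in replicates 2 and 3. Camera gave an adjusted p of 0.00198, and adjusted p = 0.656 with an estimated correlation. Of 10 pericyte and smooth muscle genes 8 rose, or 10 adjusted over the list alone, including Cspg4 (4.03), Mcam (3.08), Myh11 (2.35) and Rgs5 (1.62). Its camera adjusted p of 0.0451, or adjusted p = 0.656 with an estimated correlation, was 0.0553, 0.0618 and 0.0525 without control replicate 2, control replicate 3 or irradiated replicate 3, 0.0563 with a pseudocount of 1 and 0.0596 with at least 1 FPKM in 3 libraries. After quantile normalization or median-ratio scaling, and in 5 of 6 leave-one-out fits, 5 pericyte genes rose. The mean of the pericyte genes over the controls was 1.07 in irradiated replicate 1 and 4.11 and 3.40 in replicates 2 and 3, beside means of skeletal muscle genes of 0.78, 4.94 and 3.52 and of airway genes of 2.27, 6.96 and 2.14. The endothelial and pericyte medians were 3.10 and 3.19. Over the scalings, the medullary, fibroblast, endothelial and pericyte medians stood 1.45 to 1.92, 2.26 to 2.36, 2.18 to 2.71 and 2.44 to 2.80 above the median of all genes. Adjusted over the list alone, the counts of the epithelial, fibroblast and endothelial lists were the same.

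Of 23 macrophage genes 22 rose, with a median of 2.75 (camera adjusted p = 2.5e-06; adjusted p = 0.369 with an estimated correlation). C1qa of the complement system went from 36.7 ± 3.85 to 263 ± 5.36 FPKM (SD, n = 3), and Csf1r (3.06), the growth factor receptor of macrophages, Axl (2.73), a receptor for dying cells, and Ms4a7 (2.58) rose with it. Of 22 lysosome and phagocytosis genes 21 rose, with a median of 2.36, including the protease genes Lgmn (4.43) and Ctss (2.76), Asah1 (2.11) and Itgb5 (3.74). The camera adjusted p was 3.67e-06, and adjusted p = 0.415 with an estimated correlation. Among 19 dendritic cell genes 10 rose, led by the antigen-presenting genes H2-Eb1 (2.34), H2-Ab1 (2.08) and H2-Aa (1.74) and by Cd80 (1.96), while Clec9a (0.86), Xcr1 (-0.35) and Siglech (-0.25), which mark dendritic cell subsets, did not pass. The dendritic median was 0.86 (camera adjusted p = 0.0385; adjusted p = 0.407 with an estimated correlation), and the call was lost after quantile normalization (0.116, with 7 higher and 3 lower) and without control replicate 3 (0.0563). Macrophage, lysosome and dendritic medians stood 2.34 to 2.66, 1.95 to 2.31 and 0.46 to 0.59 above the median of all genes over the scalings. These 3 counts did not change adjusted over the list alone.

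Genes of blood and fat varied between the irradiated libraries. Of 12 adipocyte genes 11 rose, including Lpl (3.06), Pparg (2.83), Cfd (4.27) and Fabp4 (4.15), and their mean over the controls was 1.69 in irradiated replicate 1 against 5.85 and 4.41 in replicates 2 and 3. Their median was 4.04, or 3.52 to 3.66 above that of all genes over the scalings. The camera adjusted p was 0.0321, adjusted p = 0.656 with an estimated correlation, and 0.0529, with 7 genes higher, without control replicate 3. Of 7 erythroid genes only Epor passed (1.92, and 0.24 with limma adjusted p = 0.704 after quantile normalization), and the haemoglobin gene Hba-a1 measured 14.5 ± 6.31 FPKM in controls and 828 ± 1152 FPKM in irradiated thymus (SD, n = 3, limma adjusted p = 0.506). Without irradiated replicate 1 its log2 fold change was 5.96 (adjusted p = 0.000262), and without irradiated replicate 2 it was -0.25. Hba-a1 has a near-identical copy, so its level is uncertain. Among 14 genes of neutrophils and other granulocytes (the neutrophil list) 5 rose, including Mmp9 (2.85), Retnlg (3.03), Siglecf (2.04) and Ltf. Ltf, also an airway gland gene, measured 285 FPKM in irradiated replicate 2 and 8.56 and 16.5 FPKM in replicates 1 and 3, and its log2 fold change was 2.68 without irradiated replicate 2. Its call was lost without control replicates 1 and 3 (limma adjusted p = 0.0566 and 0.0502). The call for Siglecf was lost after quantile normalization (limma adjusted p = 0.553). Of 14 B and plasma cell genes 5 rose, including Sdc1 (3.28) and Cd22 (2.75), and 2 fell, the list median (-0.20) and mean (0.38) differing in sign. Of 12 natural killer and innate lymphoid genes 6 rose, including Rora (2.02) and Il2rb (1.43), and 2 fell, including Gata3 (-1.65); the list median of 0.89 turned to -0.38 after quantile normalization. There 3 neutrophil genes rose and 1 fell, 4 B cell genes rose and 8 fell, and 3 natural killer genes rose and 4 fell, while median-ratio scaling gave 3 and 3 for B cells. Without irradiated replicate 1, 10 neutrophil and 6 erythroid genes rose, and in the leave-one-out fits as few as 3 neutrophil genes rose and as few as 3 B cell genes rose and 0 fell. In irradiated replicates 1, 2 and 3 the list means over the controls were -3.24, 4.94 and 2.75 for erythroid, 0.20, 2.82 and 1.64 for neutrophil and -0.78, 1.05 and 0.87 for B cell genes. The camera adjusted p values of the erythroid, neutrophil, B cell and natural killer lists were 0.935, 0.456, 0.663 and 0.636. Adjusted over the list alone, the counts of all 5 lists were the same.

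Interferon, inflammatory and hormone response genes were higher. A smaller thymocyte share, weighed below for other lists, could also raise them, and this was not tested. Of 26 interferon response genes 23 rose, or 26 adjusted over the list alone, among them the antiviral genes Oasl2 (3.32), Ifih1 (2.17) and Iigp1 (2.83) and Gbp3 (2.69). Their mean over the controls was 1.02 in irradiated replicate 1 and 2.86 and 3.51 in replicates 2 and 3. The median was 2.55 (camera adjusted p = 0.00125; adjusted p = 0.656 with an estimated correlation). Of 21 inflammatory cytokine and NF-kappaB genes 16 rose, including Icam1 (1.83), Il1rn (2.75), Cxcl1 (2.55) and Il1a (1.96), and Tnfaip3, an inhibitor of the pathway, fell by 0.54. The mean of this list over the controls was 0.92, 1.82 and 2.79 in irradiated replicates 1, 2 and 3. The camera adjusted p was 0.0321, and adjusted p = 0.656 with an estimated correlation; the calls for Cxcl1 and Il1a were lost after quantile normalization, at adjusted p of 0.0764 and 0.256, where 5 genes of the list rose and 1 fell. Of 14 glucocorticoid response genes 10 rose, led by the metallothionein genes Mt1 and Mt2 (4.36), which metals and inflammation also induce, and by Sgk1 (2.65) and Dusp1 (1.44), while Tsc22d3 (0.63) and Fkbp5 (-0.81), direct targets of the glucocorticoid receptor, did not pass. Its camera adjusted p of 0.0471, or adjusted p = 0.656 with an estimated correlation, was 0.182 without irradiated replicate 1, where 10 genes rose and 2 fell, 0.0588 and 0.0585 without control replicates 1 and 2, 0.0503 with a pseudocount of 1 and 0.0516 after scaling to the summed FPKM. Of 15 immediate early genes 9 rose, including Jun (3.53), Ier3 (3.67), Klf4 (2.70) and Atf3 (2.73), and Nr4a1 (-0.96) and Myc (-0.52) fell (camera adjusted p = 0.291), with 7 higher and 4 lower after quantile normalization and 7 and 3 after median-ratio scaling, and 8 and 0 without control replicate 2 or 3. Fry called the immediate early list as higher (adjusted p = 0.0230). Of 13 thymus regeneration factor genes 10 rose, or 11 adjusted over the list alone, including Bmpr2 (2.39), Ccl11 (2.61) and the stem cell factor gene Kitl (1.66), and Tnfsf11 fell (-0.74). This list (camera adjusted p = 0.0443; adjusted p = 0.415 with an estimated correlation) was at 0.0978 without irradiated replicate 1 and 0.0522 with at least 1 FPKM in 3 libraries, and 6 of its genes rose and 1 fell after quantile normalization. The interferon median stood 2.15 to 2.21 above that of all genes over the scalings. The inflammatory, glucocorticoid and regeneration medians were 1.83, 1.65 and 1.88, and stood 1.07 to 1.43, 1.25 to 1.31 and 1.00 to 1.53 above it. Adjusted over the list alone, the counts of the inflammatory, glucocorticoid and immediate early lists were the same.

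The series is about the PI3K-AKT pathway, which relays signals of growth factor receptors and of matrix contacts to cell survival and growth. The receptor, ligand and matrix genes at its start rose almost throughout, while its core genes went both ways. Of 59 receptor and ligand genes 51 rose and none fell, with a median log2 fold change of 2.37. Osmr, the oncostatin M receptor, went from 3.62 ± 0.706 to 46.9 ± 5.63 FPKM (SD, n = 3), and Egfr (3.10), Csf1r (3.06) and Pdgfra (2.98) rose as well. Of 51 matrix and integrin genes 44 rose, or 46 adjusted over the list alone, including the laminin genes Lama5 (4.04) and Lamb1 (3.79), the collagen gene Col1a2 (3.04) and Itgb5 (3.74), and Itga4, an integrin of lymphocytes, fell by 0.94. Their median was 2.92. The receptor and matrix lists passed camera at adjusted p of 3.09e-07 and 1.24e-07, and each had adjusted p = 0.407 with an estimated correlation. They stood 1.42 to 1.97 and 2.26 to 2.52 above the median of all genes over the scalings. The mean of the matrix genes over the controls was 1.98 in irradiated replicate 1 and 3.05 and 2.85 in replicates 2 and 3. Many of these genes are also markers of stroma, vessels or macrophages: Csf1r, Pdgfra, Flt1, Tek and Vwf stand in both kinds of list.

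Of 46 core PI3K-AKT genes 15 rose and 12 fell, with the same counts adjusted over the list alone. Inppl1, a lipid phosphatase gene, went from 1.29 ± 0.173 to 16.1 ± 5.65 FPKM (SD, n = 3), and the PI3K subunit genes Pik3cb (1.80) and Pik3r2 (1.57) and Akt1 (0.58) rose. Ccnd3, a cyclin of thymocyte proliferation, went from 126 ± 9.18 to 45.0 ± 10.0 FPKM, and Pdpk1, a kinase that activates AKT, fell by 0.87 on the log2 scale, Rictor by 1.01 and Rps6kb1 by 1.41. Pik3ca (-0.32), Akt2 (0.48) and Mtor (0.46) did not pass. The median (0.10) and the camera direction (down, adjusted p = 0.395) differed in sign, and the median was -0.10 after quantile normalization and -0.28 after median-ratio scaling, with 10 higher and 14 lower in the former and 9 and 17 in the latter. After quantile normalization 33 receptor and ligand genes rose and 2 fell. Over the 3 lists, 110 of 156 genes rose and 13 fell, against 78 and 18 after quantile normalization.

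**Figure D3:**
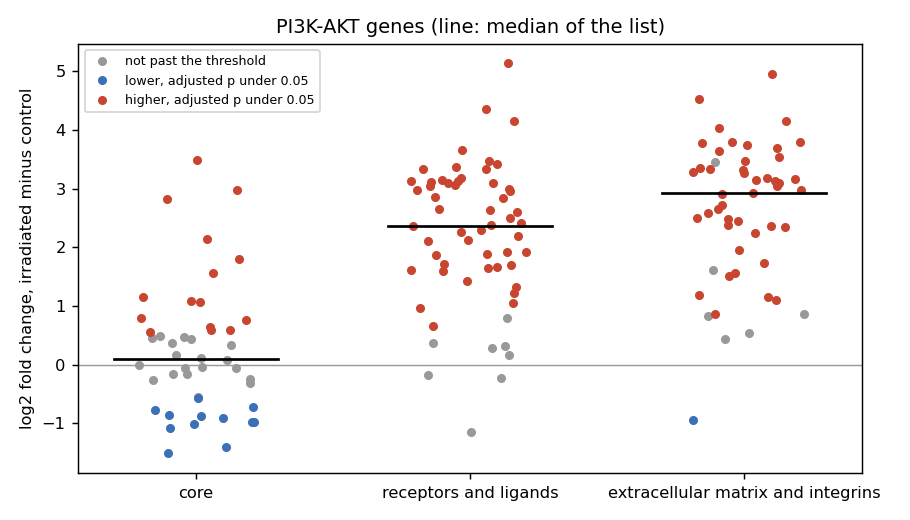
Log2 fold change (irradiated minus control) of each tested gene of the 3 PI3K-AKT lists (red, higher and blue, lower at adjusted p under 0.05; grey, not past it), with the list median as a line. The medians are 0.10 for core genes, 2.37 for receptors and ligands and 2.92 for matrix and integrin genes; that of the core genes is below 0 after quantile normalization and median-ratio scaling.

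The second comparison asks the same of long non-coding RNA (lncRNA). The lncRNA Trp53cor1 (lincRNA-p21), a p53 target (chromosome 17, 29057430 to 29079179), rose from 0.0473 ± 0.0250 to 1.99 ± 0.315 FPKM (SD, n = 3), a log2 fold change of 3.83 ± 0.39 (SE, limma adjusted p = 0.000329). The size of this change depended on the pseudocount: it was 1.51 with a pseudocount of 1 and 5.2 with 0.01. Pvt1, the neighbour of Myc (chromosome 15, 62037986 to 62378096), rose from 1.64 ± 0.167 to 11.2 ± 2.83 FPKM (2.68), and Lncpint, another p53 target, from 14.2 ± 0.609 to 49.4 ± 14.7 FPKM (1.75). Mir142hg, host of a microRNA of blood cells, fell from 109 ± 7.11 to 24.6 ± 7.80 FPKM (-2.20), and Mir17hg, host of a microRNA cluster of proliferating cells, from 10.7 ± 1.60 to 2.19 ± 1.00 FPKM (-2.31).

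Of 62 known lncRNA genes fixed in advance, 44 were tested, 12 rose and 18 fell, or 13 and 19 adjusted over the list alone. After quantile normalization 15 rose and 11 fell, after median-ratio scaling 16 and 12, and after scaling to the summed FPKM 15 and 14. Besides those above, Meg3 (2.42), Rian (1.40), Mir99ahg (2.38), Snhg18 (2.82), Bvht (2.51), Morrbid (2.52), Peg13 (1.60), Mir22hg (1.46) and Firre (0.77) rose. Lockd (-3.32), Nespas (-3.39), Mirt1 (-2.48), 4930503L19Rik (-1.62), Kcnq1ot1 (-1.50), Gm19585 (-1.37), Dleu2 (-1.30), Ftx (-1.07) and Jpx (-1.03) fell. The small nucleolar RNA host genes Snhg1 (-1.32), Snhg3 (-0.79), Snhg5 (-1.39), Snhg6 (-1.05), Snhg8 (-1.14) and Gas5 (-0.90) fell too, as did Tug1 (-0.78), but these 7 calls were lost after quantile normalization, at adjusted p of 0.105 to 0.410, and without control replicate 1, at 0.0522 to 0.122. Gm19585 lost its call in 4 of 6 leave-one-out fits, at limma adjusted p of 0.0613 to 0.0722, and Firre in 4 of 6, at 0.0595 to 0.130. Malat1 (0.12) and Neat1 (0.06), abundant nuclear lncRNAs, did not pass.

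The lncRNA table mostly holds non-coding transcripts of genes that also have an mRNA: of its 9421 tested genes, 1270 were of the type lncRNA. Over the whole, 1492 were higher and 2840 lower, 34.4% of the calls being higher, with a median log2 fold change of -0.44. The split was 1698 higher and 1827 lower after quantile normalization, 2030 and 1628 after median-ratio scaling, and 1839 and 1845 after scaling to the summed FPKM. With median-ratio factors taken from the mRNA table it was 1135 higher and 4403 lower. It was 1275 and 1656 without control replicate 3, 1217 and 1765 without control replicate 2 and 1482 and 3823 without irradiated replicate 1. With each of 19247 transcripts tested alone, 1590 were higher and 4726 lower. In the authors' deposited table, of the lncRNA-table transcripts, 1999 were higher and 941 lower at an adjusted p under 0.05, of 41029 with a value, a balance opposite to that of the limma test. Among the 1270 lncRNA genes, 233 were higher and 400 lower, against 240 and 330, 299 and 275, 281 and 300, and 178 and 582 under these scalings in turn.

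Among the largest changes of the lncRNA table were those of the recombination gene Dntt and of a lysosomal gene of antigen-presenting cells. Non-coding transcripts of Dntt (-7.92), Chrna9 (-7.49) and Hist1h3f (-7.42) fell beside Dgkeos (-7.74), an antisense gene of Dgke, and Gm15340 went from 15.9, 15.7 and 17.8 FPKM in the controls to being listed at 0 in all irradiated libraries. Ifi30 (6.31), typed as a lncRNA gene in the deposited table although it encodes a lysosomal thiol reductase, Gm12840 (5.96), Tm4sf1 (5.23) and Csrp2 (5.07) rose, and CAAA01147332.1, listed at 0 in all controls, measured 13.0, 13.1 and 12.0 FPKM in the irradiated libraries. In irradiated replicates 1, 2 and 3, Tm4sf1 measured 0.494, 22.0 and 22.0 FPKM and Csrp2 13.4, 25.2 and 0.0299 FPKM, and over leave-one-out fits their log2 fold changes ran from 4.36 to 6.97 and from 3.65 to 7.45. The call for Csrp2 (limma adjusted p = 0.0376) was lost without any library other than irradiated replicate 3, at 0.0819 to 0.137, and after quantile normalization (0.0668). Among genes typed lncRNA alone, a set added after the values were seen, Gm20634 (4.35) and 4631405K08Rik (3.94) also rose, Gm27230 (-6.91) and Gm13919 (-6.77) fell, and Gm27255 went from 9.91, 12.7 and 14.5 FPKM to being listed at 0. Strand use in counting is not given in the sources used here, so values of antisense or overlapping transcripts, such as Dgkeos, Gm13919, Gm20634, Nespas and Kcnq1ot1, are uncertain.

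The third comparison sets each lncRNA gene beside the nearest protein-coding gene. Trp53cor1 and the neighbouring Cdkn1a, 11800 bases away, both rose (3.83 and 5.04), as did Snhg18 and Sema5a (2.82 and 2.70). Lockd and the cell cycle inhibitor gene Cdkn1b, 3579 bases away, both fell (-3.32 and -0.97), as did Gm27255 and Mns1. Pvt1 rose while Myc, 47612 bases away, fell (2.68 and -0.52), and Nespas fell while the overlapping Gnas rose (-3.39 and 1.65). Across 1204 pairs within 100 kb, Spearman's rho of the log2 fold changes was 0.509 (permutation p = 1e-05, two-sided, the smallest 100000 permutations can give). Of 589 lncRNA genes past the test, 74.9% had a neighbour that moved the same way, against 50.5% with permuted neighbours (permutation p = 1e-05, one-sided). Gene models overlapped in 733 pairs, and in the 471 pairs that did not overlap rho was 0.453 and the share 73.0%. These correlations run across genes, which are not independent replicates. With a smaller thymocyte share, neighbours expressed in the same cells would also move together, which permuted neighbours do not reproduce. This was not tested, so the values do not show that a lncRNA acts on its neighbour.

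**Figure D4:**
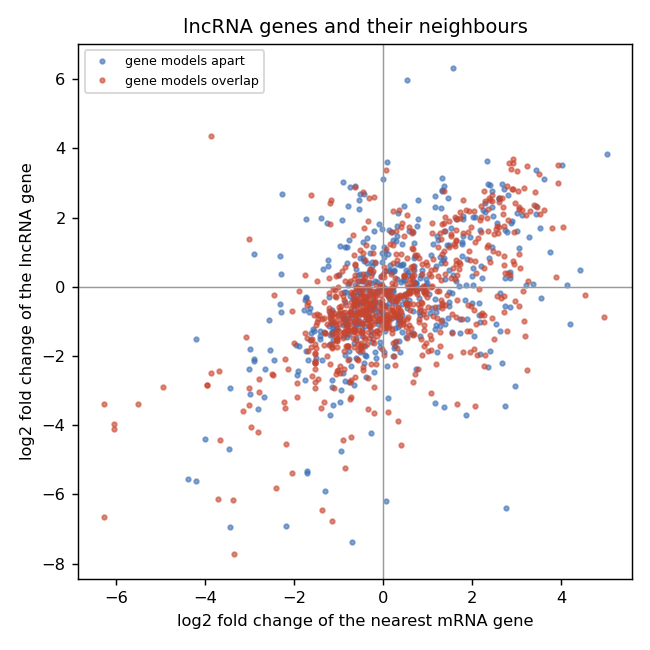
Log2 fold change (irradiated minus control) of 1204 lncRNA genes against that of the nearest tested mRNA-table gene within 100 kb (red, gene models that overlap; blue, gene models apart). Spearman's rho across all pairs is 0.509 and across pairs whose models do not overlap 0.453.

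The last comparison describes gene classes that bear on RNA quality and composition, as shares of summed FPKM in the mRNA table, where an exact permutation test of 3 against 3 cannot go below p = 0.1. Histone genes made up 13.9% ± 1.22 of summed FPKM in controls and 1.12% ± 0.881 in irradiated thymus (SD, n = 3, exact two-sided permutation p = 0.1). Most histone mRNAs carry no poly(A) tail, and how they entered libraries labelled as polyadenylated RNA was not tested. Mitochondrially encoded genes made up 2.58% ± 0.240 and 4.08% ± 2.78 (exact permutation p = 0.6), with 7.13% in irradiated replicate 2. Ribosomal protein genes made up 4.66% ± 0.185 and 3.89% ± 0.811 (exact permutation p = 0.3), erythroid genes 0.0358% ± 0.0163 and 0.908% ± 1.25 (exact permutation p = 0.4), and the 20 most abundant genes 10.1% ± 0.739 and 9.35% ± 2.53 (exact permutation p = 0.7). The lncRNA table held 23.0% ± 0.707 and 18.2% ± 5.78 of the FPKM of both tables (exact permutation p = 0.4). Without irradiated replicate 1 the differences in points, irradiated minus control, were 2.68 for mitochondrial, -1.18 for ribosomal protein and 1.33 for erythroid genes, 0.470 for the 20 most abundant genes and -8.16 for the lncRNA table. Without irradiated replicate 2 they were -0.0343, -0.372, 0.162, -2.05 and -2.74. With all libraries but without the 20 most abundant genes of each, they were -0.0538 for mitochondrial, -0.617 for ribosomal protein, 0.224 for erythroid and -7.41 for histone genes. With those genes kept, the 4 differences were 1.49, -0.766, 0.872 and -12.7. Benjamini-Hochberg adjustment over these 6 tests was not needed for a call, since none reached p under 0.05. None of the 13 mitochondrial genes passed limma (mt-Co2 at 1.44, adjusted p = 0.0994, and 2.22, adjusted p = 0.00108, without irradiated replicate 1; camera adjusted p = 0.99). Of 34 ribosomal protein genes Rpl7 (-1.02), Rps20 (-0.42), Rpl5 (-0.80) and Rps3 (-0.78) fell and Rps2 (0.63) rose, and none passed adjusted over the list alone. The list median of -0.07 (camera adjusted p = 0.046; adjusted p = 0.656 with an estimated correlation) turned to 0.04 after quantile normalization (adjusted p = 0.5) and without irradiated replicate 2 (0.179). The call was also lost without control replicate 2 (camera adjusted p = 0.0568), with a pseudocount of 1 (0.0531) and with at least 1 FPKM in 3 libraries (0.079), and the 4 falls were lost without any of the controls. Its median lay -0.48 to 0.11 from that of all genes over the scalings, and 1 gene rose and 1 fell after quantile normalization, and 10 fell after median-ratio scaling. Fry did not call the ribosomal protein list (adjusted p = 0.375).

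In the authors' deposited table, 6214 genes were higher and 2676 lower at an adjusted p under 0.05, of 19142 genes with a value. Between the authors' deposited table and the limma test, 7109 genes were called in the same direction and 0 in opposite directions. The authors' deposited table called 384 tested genes that limma did not, and limma 1744 that the table did not. The log2 fold changes of the authors' deposited table lay a median of -0.149 from those given here, with a Pearson r of 0.964 across genes.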

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

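The scalings by median ratio and summed FPKM, the lncRNA-gene-only test, the mRNA-table factors and the authors' deposited table were chosen after seeing results. So were the group separation alternatives and the leave-one-out shares. The shares without the most abundant genes were fixed in advance. The count of called mRNA genes (8853) ran from 7096 to 10196 over the leave-one-out fits, from 7904 to 9753 over scalings, pseudocounts and filters, and to 6329 at adjusted p under 0.01. The lncRNA-table count (4332) ran from 2931 to 5305 over the leave-one-out fits, was 5538 with mRNA-table factors and 6316 with each of 19247 transcripts tested alone, and fell to 2260 at adjusted p under 0.01, a stricter threshold, and to 672 with lncRNA genes only, where 1270 genes were tested. The PI3K-AKT count (123) ran from 96 to 136 over all settings but the stricter thresholds. Of the 22 called lists 0 passed camera with an estimated correlation, which was as high as 0.962 in the interferon list, while fry called 25. Fry added the early thymocyte, cortical epithelial, natural killer and immediate early lists and left out the ribosomal protein list. Unlike camera, fry does not compare a list with other genes. Its calls therefore do not set a list apart from the rise over all genes (median log2 fold change 0.40). With a pseudocount of 1 or with at least 1 FPKM in 3 libraries 19 lists passed camera at the preset correlation, and 19 to 22 in the leave-one-out fits. Those that lost the call with the pseudocount were the pericyte, glucocorticoid and ribosomal protein lists, and with the filter the pericyte, regeneration and ribosomal protein lists. The share of variance on the first principal component (83.7%) was 82.3 to 90.9% in the leave-one-out fits and 78.2% after quantile normalization, and the cause was not tested. The neighbour correlation (0.509) stayed between 0.453 and 0.538 over distances, leave-one-out fits and scaling.

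After quantile normalization 2 called results reversed, the ribosomal protein list at a median of 0.0400 (camera adjusted p = 0.5) and Foxp3 at -0.22 (limma adjusted p = 0.609), and the cause was not tested. The medians of the BCL2, regulatory T cell, natural killer and PI3K-AKT core lists, which camera did not call, also changed sign, to -0.07, -0.22, -0.38 and -0.10. Of 152 named mRNA genes 13 lost and 1 gained its call under quantile normalization, 5 to 8 lost it without each control or irradiated replicate 2 or 3, and 7 gained it without irradiated replicate 1. Of 45 named lncRNA-table genes 8 lost it under quantile normalization and 8 or 9 in all leave-one-out fits but that without irradiated replicate 1, where 1 did. Leave-one-out fits have fewer libraries.

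The libraries of the 2 groups share only replicate numbers, whose deviations correlated at 0.0596, -0.0433 and 0.0516, so the numbers do not pair them, and not every library correlated best with its own number. With a replicate block 8355 mRNA genes, 3936 lncRNA-table genes, 22 lists and 123 PI3K-AKT genes passed. Alternatives that need counts (other count scalings and count-based tests) were not run because the tables hold FPKM, and single mRNA transcripts were not tested because their values repeat the gene's. In simulated data 13.2% of log2 fold changes of 1 in the lncRNA table were called, against 44.0% in the mRNA table, and depth was not varied. Few simulated genes were changed, while 63.2% of the real mRNA genes were called, so these rates need not hold for the real data.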

Other observations

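All patterns weighed here, their tests, the gene families and the lists of other tissues were chosen after seeing results. Histone genes, which are copied in S phase, fell almost without exception: 65 of 66 were lower and none higher under each of the 4 scalings, with a median log2 fold change of -3.97. Hist1h4k went from 1109 ± 139 to 101 ± 39.8 FPKM and Hist2h2bb from 1072 ± 81.8 to 74.4 ± 38.6 FPKM (SD, n = 3), although near-identical copies make single histone genes uncertain. Of 349 zinc finger genes of the Zfp kind, 138 fell and 57 rose, and 223 and 21 did so after quantile normalization. Zfp280d (-2.19), Zfp770 (-1.76) and Zfp846 (-1.88) fell, while Zfp503 (3.37), Zfp462 (2.79) and Zfp608 (2.18) rose. Of 28 cytochrome P450 genes 24 rose, including Cyp1b1 (2.77) and Cyp2j9 (3.56), with 16 higher and 2 lower after quantile normalization, and of 23 Ccl chemokine genes 15 rose, or 11 after quantile normalization, including Ccl6 (4.52), Ccl8 (4.49) and Ccl9 (4.01) of myeloid cells.

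Genes of tissues beside the thymus differed between irradiated libraries. Airway secretory genes were highest in irradiated replicate 2: Scgb3a1 measured 0.531, 252 and 1.06 FPKM and Cyp2f2 10.9, 288 and 6.05 FPKM in irradiated replicates 1, 2 and 3. Their list means over the controls were 2.27, 6.96 and 2.14, those of skeletal muscle 0.78, 4.94 and 3.52, and those of lung alveoli 0.81, 2.26 and 0.42. The parathyroid hormone gene Pth measured 27.2, 27.1 and 5.97 FPKM in the irradiated libraries and 4.25, 5.88 and 0.257 FPKM in the controls. Gm42418, which overlaps ribosomal RNA, measured 8.24, 6923 and 6902 FPKM in the controls and 7946, 2018 and 2391 FPKM in the irradiated libraries.

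Genes of stroma, medullary epithelium and macrophages rose as thymocyte genes fell, which a smaller thymocyte share would also bring about without a change in any cell. Such a share alone would lift genes of all other cell types equally only if thymocytes did not express them. Over 10 types the medians ran from -0.20 to 3.19 and differed (permutation p = 1e-05). Thymocytes also express some listed genes, such as Thy1 (-2.91) in the fibroblast list. The permutation also treats genes that move together as independent. The difference therefore does not rule out a lower thymocyte share alone. Over medullary epithelium, fibroblasts, endothelium, pericytes and macrophages the medians ran from 2.32 to 3.19, and equal lifts could not be ruled out (permutation p = 0.0808). These 5 were chosen after the medians were seen and lie close together, so this test does not decide either. A lower thymocyte share thus stays open for all these cell types. It was not tested for the p53 target, interferon, inflammatory, glucocorticoid, regeneration and PI3K-AKT lists, where it stays open too. Nor was it tested for the falls of mitosis, DNA replication, DNA repair, T cell receptor and histone genes, where it also stays open. Library scaling did not account for the rise of the 5 lists of medullary epithelium, fibroblasts, endothelium, pericytes and macrophages. The lowest of their medians, that of medullary epithelium after quantile normalization, stood 1.45 above all genes (95% bootstrap interval over 2000 draws 0.997 to 2.11). Neither did tissue from outside the thymus in irradiated replicate 2 alone. Without that library the lowest median, that of medullary epithelium, was 2.27 (1.53 to 2.40). Irradiated replicate 3 was also high in skeletal muscle and adipocyte genes (list means over the controls 3.52 and 4.41). Outside tissue in replicate 3 stays open, since no test left out both libraries. Cell counts, sorted cells or single-cell data would tell shares from changes within cells.

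Irradiated replicate 1 lay nearer to the controls than replicates 2 and 3. Mixed-in control RNA is limited to a share of 0.0352 by the third lowest ratio to the control mean among 17 double-positive thymocyte genes (lowest 0.0036). The genes that rose would need a median share of 0.515, and those that fell 0.1065. Both sets were chosen by their change in replicates 2 and 3 and measured against these, which can overstate the shares needed. Other tissue in replicates 2 and 3 stays open. Over 60 mitosis and replication genes replicate 1 stood at 0.714 of the way from the controls to the other 2 (95% bootstrap interval 0.698 to 0.772), but RNA of non-dividing tissue would also lower these genes further in replicates 2 and 3, so the value does not decide. Dose and time per animal were not tested.

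Non-coding transcripts fell against the mRNA of the same gene, with a median shift of -0.42 over 7983 genes. Their median log2 ratio to that mRNA was -1.72, -1.70 and -1.67 in control replicates 1, 2 and 3. In irradiated replicates 1, 2 and 3 it was -1.95, -2.37 and -2.28. Other tissue in irradiated replicates 2 and 3 was not tested as a cause, and the intervals below run over genes, not libraries. The mRNA has 1 FPKM value per gene, while the non-coding value is a sum over transcripts. How the gene value was formed is not given in the sources used here, and this difference was not tested as a cause. Separate scaling of the tables did not account for the shift, since the FPKM worth of 1 fragment differed by at most 4.24e-06 on the log2 scale. Neither did values near the floor, since genes averaging 5 FPKM or more in both tables shifted by -0.32 (95% bootstrap interval -0.34 to -0.30, 2476 genes). Whether less intron-retaining RNA explains the shift stays open. Retained-intron and processed transcripts of the same gene differed by -0.0507 (-0.0948 to -0.0131, 1411 genes). Processed transcripts are non-coding as well and fell too, with a median log2 fold change of -0.53 against -0.57 for retained introns. The comparison thus shows only that retained introns fell little more than other non-coding transcripts.

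With 3 and 3 libraries there are 10 splits, and the share that reach the real count cannot go under 0.1. The real split gave 8853 mRNA genes, 4332 lncRNA-table genes and 123 PI3K-AKT genes, 1 of 10 splits reached each, and the highest other count was 0. The real split gave 22 lists by camera, 3 of 10 splits reached it, and the highest other count was 23. By fry the real split gave 25 lists, and the highest other count was 0. Each other split mixes libraries of both groups on each side, so the group difference widens the spread within sides. Limma and fry would then call few or none whatever the cause, so the counts of 0 decide nothing.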
